A study of Mus musculus with 12 samples.

How the data were processed

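Bulk RNA sequencing was done on brain RNA from 12 mice labelled 5xFAD, a transgenic model of amyloid deposition. Per the labels, the mice fell into 4 groups of 3, called Control, PBS, ShK-223 and PAP-1, each library came from its own mouse, and the tissue was whole brain. Dose, route, duration, age and what sets Control apart from PBS are not given in the sources used here. Each library also carries 1 of the batch names B, C and CH, and what these stand for is not given in the sources used here. PBS has no library in batch B, ShK-223 none in C and PAP-1 none in CH. RNA integrity numbers ran from 7.8 to 8.9, per the labels.

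The authors deposited 1 table of whole-number read counts per gene with 21643 rows. Reads were aligned with STAR 2.7.11a to GRCm38 (mm10), per the submitters' processing notes, which also name R 4.3.2 and DESeq2 1.40.2. The counting tool, its strand setting and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies may therefore be shared. This may hold for the keratin, histocompatibility and haemoglobin genes named in the report, and for Ntn5 and Sec1, which overlap on opposite strands. Column names carry the library names and were matched to samples through them. Repeated gene names (22 rows) were kept as separate rows, and 2893 rows had 0 counts in all libraries. Total counts per library ran from 14364013 to 19048551. Between any 2 libraries the chi-square per gene was at least 7.16, far above sampling noise, so no library was a copy of another.

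From the deposited counts, genes were filtered with filterByExpr, which left 15061, and libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3. The quasi-likelihood test of edgeR was fitted to all 12 libraries with the group as the term, so that all groups share 1 estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method within each of 7 comparisons, with calls at 0.05. Standard errors (SE) of log2 fold changes are the fold change over the root of the test's F value and are approximate, above all where a group is near 0. CPM are from the cpm function of edgeR on TMM-scaled totals, with SD over 3 libraries. A fold against a group with 0 counts in every library was computed against a floor of 3 counts over that group, which covers counting error only.

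Gene lists (40 with 775 symbols, of which 765 matched the table, older symbols through the RefSeq synonyms) covered microglial and immune states, neuronal, metabolic and stress genes, and markers of other cell types and brain regions. The 39 lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry. The genes named in the report follow a rule. It takes up to 8 higher and 8 lower genes with the largest fold change among called genes without overlap between groups and a mean log2 CPM of at least 1, predicted models left out. Where fewer pass, it fills to 8 with the smallest p. It adds 12 fixed genes and up to 4 members per called list, some of which are given. Results for some of the genes that follow from this rule are not reported here. The lists, this rule, the main tests and the first set of other settings were fixed before the data were examined. A cerebellar index per library, the mean over the cerebellum list of each gene's CPM over that of its highest library, was added after the data were seen.

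The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, 2 other filters, batch or RNA integrity as an added term, a fit of the compared groups alone, a threshold of 0.1 and leaving out each library in turn. Added later were the cerebellar index as a term, a fit without Control 2 and PAP-1 1, and thinning of all libraries to the smallest total. Sex as a term was not fitted, because no library held more than 2 counts of any of 4 Y-linked genes, so there was no sign of both sexes.

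The 3 gene-level tools and the list tests were run on simulated data with known changes. For ShK-223 against PBS, with 14953 genes tested, edgeR recovered 90.9% of genes changed 4-fold, 41.8% of those changed 2-fold and 5.97% of those changed 1.5-fold, with 3 false calls. With the cerebellar index as a term it recovered 47.0% and 1.49% of the 4-fold and 2-fold changes, in simulated counts without a tissue difference between libraries. On the same data without that term, DESeq2 made 31 false calls among 15061 genes and limma-voom 3. Replicate numbers follow the order of the samples and pair nothing. Gene coordinates are from GENCODE on GRCm38, where 108 of 111 genes looked up were found once.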

Results

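Gene expression was measured by RNA sequencing in 12 libraries of brain tissue from mice of the 5xFAD amyloid model, with 3 mice in each of the groups Control, PBS, ShK-223 and PAP-1. ShK-223 is a peptide derived from a sea anemone toxin and PAP-1 a small molecule. Both block the potassium channel Kv1.3, which is encoded by Kcna3 and is present on microglia and T cells. The series addresses what Kv1.3 inhibition does to the brain in amyloid pathology. Total counts ran from 14364013 to 19048551 per library, and 16662 to 17142 genes had at least 1 count.

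Tissue markers differed between libraries of the same group. Gabra6, a GABA receptor subunit of cerebellar granule cells (GRCm38 chromosome 11, 42306437 to 42321072), was at 415 ± 34.6 CPM (SD, n = 3) in PBS and 0.271 ± 0.193 CPM in ShK-223. In Control it was at 1.23, 332 and 0.112 CPM in libraries 1, 2 and 3. In PAP-1 it was at 58.4, 0.114 and 0.518 CPM. The cerebellar index was 0.858 to 0.984 in PBS, 0.812 in Control 2, 0.199 in PAP-1 1 and 0.0443 to 0.0590 in the other 7 libraries. The first principal component held 62.8% of the variance. Striatal transcripts also varied: Adora2a was at 104 and 91.1 CPM in Control 1 and 3, 1.34 CPM in Control 2, and 2.18, 72.8 and 32.7 CPM in the ShK-223 libraries. All 12 libraries are labelled whole brain. Across genes Control 2 correlated with PBS 1 at r = 0.987 and with Control 1 and 3 at r = 0.930 and 0.932. The deposited column name of Control 2 gives lane 1 and the names of the other libraries lane 7, and a wrong label of Control 2 was not excluded.

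**Figure D1:**
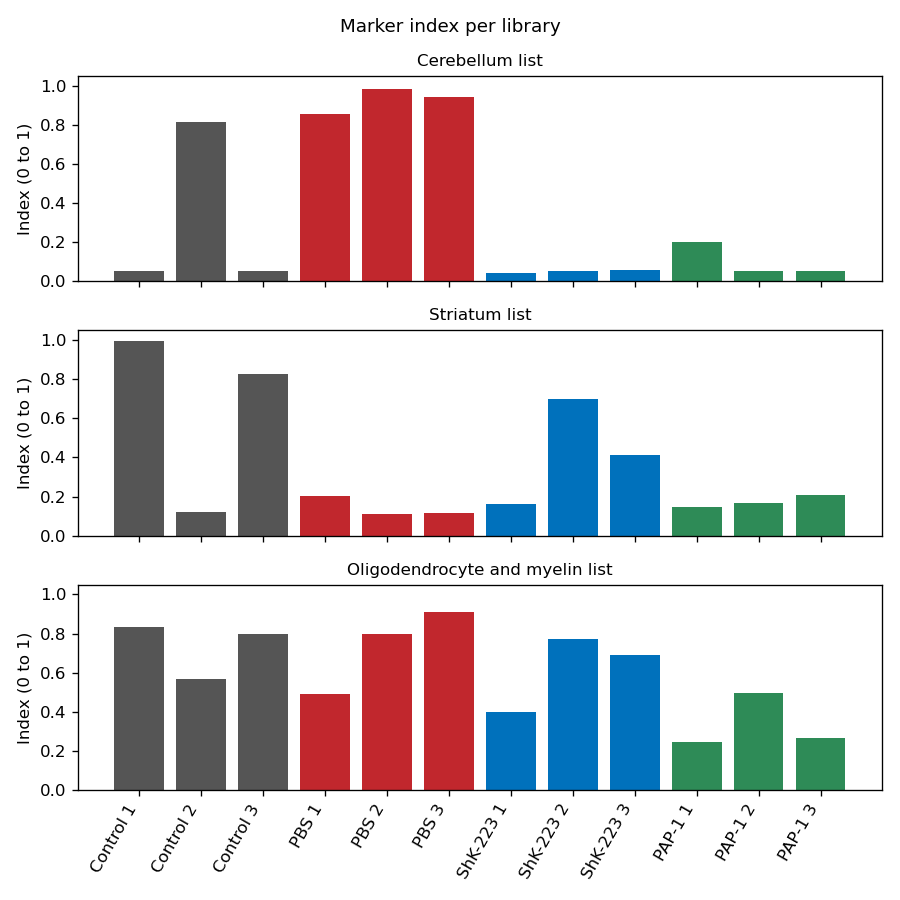
Bars give the index of the cerebellum, striatum and oligodendrocyte lists (0 to 1, relative to the highest library of each gene) for each of the 12 libraries, coloured by group. The cerebellar index lies between 0.812 and 0.984 in the 3 PBS libraries and Control 2 and at 0.199 or below in the other libraries.

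ShK-223 was compared with PBS to ask how the peptide blocker changes brain expression. Microglial, antigen-presentation, forebrain-neuron and cholesterol-synthesis genes were higher with ShK-223 than with PBS, and cerebellar genes were lower. Of 15061 genes tested, 5896 passed the edgeR quasi-likelihood test at an adjusted p of 0.05, of which 2835 were higher and 3061 lower with ShK-223. Kcna3 itself (chromosome 3, 107036169 to 107038070) rose from 2.43 ± 0.267 to 3.82 ± 0.366 CPM (log2 fold change 0.65, SE 0.22, adjusted p = 0.0394, n = 3 against 3). Without a blocker, Kcna3 was at 3.24 and 3.70 CPM in Control 1 and 3, and at 2.56 CPM in Control 2, which held cerebellar transcript. Ntn5, a netrin, rose from 0.269 ± 0.253 to 10.2 ± 2.21 CPM (5.18, SE 0.58, adjusted p = 0.00367).

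Among microglial genes, 14 of 19 genes of the homeostatic list rose and none fell (17 adjusted over the list alone), with a median log2 fold change of 1.35 (camera adjusted p = 0.000118). Camera compares a list's genes with all others at a fixed correlation between genes, and fry tests the list by itself. The list had an adjusted p = 0.83 with an estimated correlation. Tmem119 rose by 1.34 (SE 0.33) and P2ry12, a purinergic receptor of resting microglia, by 1.35 (SE 0.40, edgeR adjusted p = 0.0228). In the plaque-associated list 10 of 30 genes rose and 1 fell, the same 10 and 1 adjusted over the list alone (median 1.09, adjusted p = 0.83 with an estimated correlation). Trem2, a lipid receptor of plaque-associated microglia, rose from 22.5 ± 16.4 to 79.8 ± 18.7 CPM (1.82, SE 0.62, adjusted p = 0.0398), Lpl by 2.00 (SE 0.55) and Cd68 by 1.72 (SE 0.50). Cst7 (1.96, SE 0.73, adjusted p = 0.0543) and Itgax (1.62, SE 0.71, adjusted p = 0.0915) missed the threshold. In antigen presentation 9 of 21 genes (9 adjusted over the list alone) and in the complement and Fc receptor list 10 of 19 (15 adjusted over the list alone) rose, with Cd74 up by 2.47 (SE 0.51), H2-Ab1 by 2.09 (SE 0.57), C1ra by 2.25 (SE 0.42) and C1s1 by 1.77 (SE 0.41). Both lists had an adjusted p = 0.83 with an estimated correlation. The mean log2 CPM of the antigen-presentation list, centred per gene, was 1.14, 0.13 and 0.04 in ShK-223 1, 2 and 3. In PBS 1, 2 and 3 it was -0.575, -0.99 and -0.10, and the call held in 6 of 6 fits without 1 library. Beside these microglial and immune groups, all 16 genes of the cerebellum list were lower, and Control 2, which also held cerebellar transcript, had Trem2 at 20.3 CPM against 98.5 CPM in both Control 1 and Control 3.

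Genes of forebrain neurons rose. In the excitatory neuron list 11 of 15 genes rose and 1 fell (11 and 2 adjusted over the list alone, median 1.76, adjusted p = 0.71 with an estimated correlation). In the hippocampus and cortex list 11 of 15 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.62 with an estimated correlation). Neurod6, a transcription factor of forebrain excitatory neurons, rose by 2.82 (SE 0.36) and Fibcd1 by 3.19 (SE 0.37). Presynaptic genes rose for 11 of 25 and fell for 1 (12 and 1 adjusted over the list alone, adjusted p = 0.72 with an estimated correlation), with Syn1 up by 1.25 (SE 0.18) and Syt1 by 1.47 (SE 0.24). Postsynaptic genes rose for 14 of 26 and fell for 0 (15 and 1 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), with Grin2b, an NMDA receptor subunit, up by 2.64 (SE 0.45). Thy1 rose from 672.6 ± 74.03 to 2317 ± 478 CPM (1.78, SE 0.32, adjusted p = 0.00542). App rose by 0.36 (SE 0.09, adjusted p = 0.0115). In Control 1, 2 and 3, Thy1 was at 1841, 866 and 2191 CPM and App at 1807, 1626 and 1897 CPM. Immediate early genes rose for 10 of 25 (10 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), with Egr1 up by 2.30 (SE 0.39) and Arc by 2.61 (SE 0.59). Of the striatum list 3 of 15 rose (1 adjusted over the list alone, adjusted p = 0.88 with an estimated correlation), with Foxp1 up by 1.82 (SE 0.45).

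Sterol enzymes rose together: 14 of 22 genes of cholesterol synthesis (16 adjusted over the list alone, median 0.64, adjusted p = 0.83 with an estimated correlation), among them the regulator Srebf2 by 0.89 (SE 0.15) and Fdft1 by 1.34 (SE 0.27). Ribosomal protein genes rose for 9 of 41 (0 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), with Rpl10 up by 0.64 (SE 0.18). Of the NF-kB and cytokine list 4 of 20 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), with Tnfaip3 up by 1.17 (SE 0.25). The astrocyte list fell for 8 of 15 and rose for 2 (9 and 2 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), with S100b at -1.42 (SE 0.26) and the glutamate transporter Slc1a3 at -1.18 (SE 0.26). Apoe (0.25, SE 0.21), Gfap (1.21, SE 0.55), Snap25 (0.08, SE 0.13) and Mbp (-0.38, SE 0.33) did not pass.

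The largest falls were in cerebellar genes. Sycp1 had 0 counts in all ShK-223 libraries against 20.79 ± 1.403 CPM in PBS, so it was at least 380-fold lower, and Lbx1 likewise at least 145-fold lower. Gabra6 (-10.53, SE 3.12, adjusted p = 0.0239), Cbln3 (-10.12, SE 3.05), Nrk (-9.72, SE 2.68), Fat2 (-9.68, SE 2.98), Skor2 (-9.44, SE 2.50) and Ppp1r17 (-9.42, SE 2.71) followed. All 16 tested genes of the cerebellum list fell (16 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), with Calb1 at -2.50 (SE 0.53) and Itpr1 at -2.29 (SE 0.56). Besides Ntn5, the largest rises were in Dsc3 (5.67, SE 1.63), Krt2 (5.01, SE 1.25), Mdfic2 (4.54, SE 1.02), Bglap3 (4.44, SE 0.70), Glp2r (4.12, SE 0.78), Sec1 (4.06, SE 0.55) and Krt73 (3.98, SE 1.00). Ntn5 and Sec1 overlap on opposite strands and may share reads. With the batch as a term 4 genes passed, the median log2 change of the called genes being 0.69 against 0.79 with SE 1.23 times as large, and leaving out PBS 2, PBS 3 or ShK-223 3 left 3156, 3752 and 3744. With the cerebellar index as a term 0 passed at a median of 0.10, Trem2 and Cd68 turned to lower values, and so did the homeostatic (adjusted p = 0.000145), plaque-associated (0.000134), ribosomal (7.9e-12), striatum (4.2e-07) and complement (0.0678) lists, the cerebellum (0.0354) and astrocyte (0.628) lists turning higher. With this term the cholesterol (camera adjusted p = 0.563), antigen-presentation (0.464) and cytokine (0.464) calls ended. The striatum call held in 3 of 6 fits without 1 library, and the cytokine and astrocyte calls in 4 of 6. Within batch CH (2 ShK-223 libraries against 1 PBS library) all 5896 called genes, which these libraries helped to select, kept their direction.

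**Figure D2:**
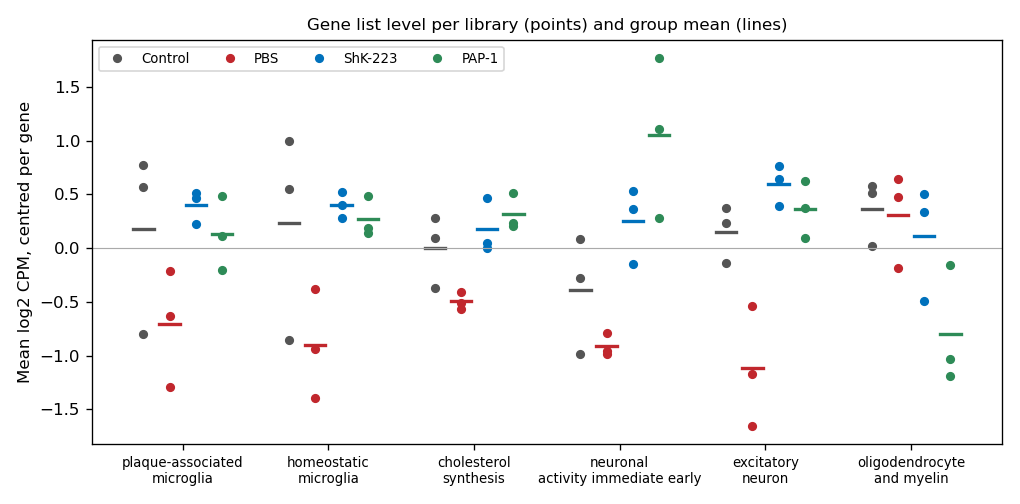
Points give the mean log2 CPM, centred per gene, of 6 gene lists in each of the 12 libraries, and lines give the mean of each group of 3. For the homeostatic microglia list, Control 2 at -0.85 lies among the PBS libraries at -0.38, -1.395 and -0.94, and Control 1 and 3 are at 1.00 and 0.55.

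PAP-1 was compared with PBS to ask the same of the small molecule. Immediate early, sterol and forebrain genes were higher with PAP-1 than with PBS, and myelin and cerebellar genes were lower. In edgeR 6589 genes passed, 3182 higher and 3407 lower with PAP-1. Immediate early genes rose for 17 of 25 (18 adjusted over the list alone, median 1.93, adjusted p = 0.95 with an estimated correlation). Egr2, an activity-induced transcription factor, rose from 0.769 ± 0.767 to 36.9 ± 31.6 CPM (5.55, SE 0.97, adjusted p = 0.00342), Junb by 3.21 (SE 0.53), Egr1 by 2.60 (SE 0.40) and Fosl2 by 1.79 (SE 0.27). The list's centred mean was 1.77, 1.11 and 0.28 (log2) in PAP-1 1, 2 and 3, and -0.79, -0.99 and -0.96 in PBS. Kcna3 rose by 0.62 (SE 0.22, adjusted p = 0.0453). It was at 3.94, 2.86 and 4.38 CPM in PAP-1 1, 2 and 3, and at 3.24, 2.56 and 3.70 CPM in Control 1, 2 and 3.

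The myelin list fell for 11 of 16 genes and rose for 0 (11 adjusted over the list alone, median -1.20, adjusted p = 0.95 with an estimated correlation). Mbp, myelin basic protein, was at 1179 ± 451 CPM with PAP-1 and 2881 ± 910 CPM with PBS (-1.29, SE 0.33, adjusted p = 0.0126), and Trf (-1.24, SE 0.27) and Ugt8a (-1.58, SE 0.38) also fell. In the amyloid processing and clearance list 13 of 24 genes fell and 3 rose (13 and 3 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation). Abca7, a lipid transporter, fell by 1.67 (SE 0.31), the sorting receptor Sorl1 by 1.26 (SE 0.26) and the protease Adam17 by 0.53 (SE 0.10). The list's centred mean was 0.149, 0.140 and 0.161 in PBS and -0.129, -0.167 and -0.164 in PAP-1. In Control 1 and 3 it was 0.013 and -0.034, and 0.105 in Control 2, which held cerebellar transcript like PBS. App rose by 0.33 (SE 0.09, adjusted p = 0.0134). Beside these groups, the myelin index was 0.245 and 0.268 in PAP-1 1 and 3 and 0.496 in PAP-1 2, against 0.492 to 0.910 in PBS.

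Cholesterol synthesis genes rose for 18 of 22 (18 adjusted over the list alone, median 0.80, adjusted p = 0.95 with an estimated correlation), with Hmgcs1 up by 1.66 (SE 0.29). Ribosomal protein genes rose for 19 of 41 (20 adjusted over the list alone, adjusted p = 0.95 with an estimated correlation), with Rps20 up by 0.68 (SE 0.16). Hippocampus and cortex genes rose for 12 of 15 and fell for 1 (13 and 1 adjusted over the list alone, adjusted p = 0.66 with an estimated correlation). Fibcd1 rose by 4.17 (SE 0.38), C1ql2 by 4.29 (SE 0.72), Slc17a7, the vesicular glutamate transporter of cortical neurons, by 1.64 (SE 0.26) and Thy1 by 1.83 (SE 0.32). The excitatory neuron list rose for 10 of 15 and fell for 1 (10 and 1 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation). Presynaptic genes rose for 13 of 25 and fell for 1 (14 and 1 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation) and postsynaptic genes rose for 13 of 26 and fell for 3 (15 and 4 adjusted over the list alone, adjusted p = 0.95 with an estimated correlation), with Syp up by 0.73 (SE 0.09), Nlgn1 by 1.17 (SE 0.14) and Grin2b by 2.64 (SE 0.45).

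Homeostatic microglia genes rose for 12 of 19 (14 adjusted over the list alone, median 1.21, adjusted p = 0.95 with an estimated correlation), among them Tmem119 by 1.28 (SE 0.33) and P2ry12 by 1.11 (SE 0.39, adjusted p = 0.0423). In the plaque-associated list 6 of 30 rose and 1 fell (0 adjusted over the list alone, adjusted p = 0.999 with an estimated correlation), with Trem2 up by 1.74 (SE 0.62, adjusted p = 0.0425), Lpl by 1.80 (SE 0.55) and Cd68 by 1.43 (SE 0.50). Antigen presentation rose for 4 of 21 (2 adjusted over the list alone, adjusted p = 0.97 with an estimated correlation), with Cd74 up by 1.89 (SE 0.51). This call ended without Control 2 and PAP-1 1 (adjusted p = 0.0753). Complement and Fc receptor genes rose for 3 of 19 (0 adjusted over the list alone, adjusted p = 0.999 with an estimated correlation), with Fcgr3 up by 1.44 (SE 0.46). Cst7 (1.62, SE 0.73), Itgax (1.46, SE 0.71), Apoe (0.30, SE 0.21), Gfap (1.01, SE 0.54) and Snap25 (-0.12, SE 0.13) did not pass. Beside these microglial groups, the cerebellar index was 0.0511 and 0.0523 in PAP-1 3 and 2 and 0.199 in PAP-1 1, against 0.858 or more in PBS.

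The cerebellum list fell for 8 of 16 genes (8 adjusted over the list alone, adjusted p = 0.95 with an estimated correlation), with Itpr1 at -2.47 (SE 0.56). The largest falls were in Skor2 (-5.32, SE 1.77), Il22b (-4.73, SE 1.69), Uncx (-4.65, SE 1.505), Zfp385c (-4.50, SE 1.51), Hes3 (-4.49, SE 1.60), Car8 (-4.36, SE 1.58), Bcl2l15 (-4.18, SE 1.33) and Lhx5 (-3.99, SE 1.42). Besides Egr2, the largest rises were in Dsc3 (7.02, SE 1.61), Krt2 (6.06, SE 1.24), Krt73 (5.34, SE 0.99), Cpne7 (4.71, SE 0.66), Ntn5 (4.63, SE 0.57), Bglap3 (4.62, SE 0.70) and Glp2r (4.55, SE 0.79). With the batch as a term 2752 genes passed (median of the called genes 0.72 against 0.76, SE 1.22 times as large), and without PBS 2 3934 passed. With the cerebellar index 0 passed at a median of 0.19, Trem2 and Cd68 turned to lower values, and so did the homeostatic (adjusted p = 0.000588), plaque-associated (4.3e-05), complement (0.00212) and ribosomal (0.00022) lists, the cerebellum list turning higher (0.000148). With the index the antigen-presentation (camera adjusted p = 0.920) and amyloid processing (0.0858) calls ended. The plaque-associated, antigen-presentation and complement calls held in 4 of 6 fits without 1 library. Within batch C (PAP-1 2 against 2 PBS libraries) all 6589 called genes, which these libraries helped to select, kept their direction.

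Both inhibitor groups were also set together against PBS, and 7548 genes passed, 3560 higher and 3988 lower. Kcna3 rose by 0.63 (SE 0.20, adjusted p = 0.0217), App by 0.34 (SE 0.08), Thy1 by 1.81 (SE 0.29), Trem2 by 1.78 (SE 0.57), P2ry12 by 1.23 (SE 0.36), Cst7 by 1.79 (SE 0.67, adjusted p = 0.0453) and Ntn5 by 4.91 (SE 0.55), and Mbp fell by 0.83 (SE 0.28, adjusted p = 0.0283). Sycp1 was at 0.524 ± 1.26 CPM over the 6 inhibitor libraries, against 20.8 CPM in PBS. Its fitted log2 value of -7.90 (SE 2.03) averages in ShK-223, a group with 0 counts, so it is larger than these CPM give and is not an exact fold. Of the lists 14 of 39 passed, 12 higher and 2 lower, and 0 with an estimated correlation. Homeostatic microglia genes rose for 15 of 19 and cholesterol synthesis genes for 17 of 22, (17 and 18 adjusted over the list alone), each with an adjusted p = 0.89 with an estimated correlation. Of the plaque-associated list 11 of 30 genes rose and 1 fell, of the complement and Fc receptor list 12 of 19 and 1, of the cytokine list 4 of 20 and 1, and of the postsynaptic list 15 of 26 and 3. Adjusted over the list alone, these were 8 and 1, 14 and 1, 4 and 1, and 15 and 4, each list with an adjusted p = 0.89 with an estimated correlation. Antigen-presentation (8 of 21), immediate early (14 of 25) and ribosomal genes (21 of 41) rose and none fell, with 8, 14 and 21 adjusted over the list alone and the same adjusted p = 0.89 with an estimated correlation. All 16 cerebellum genes fell (16 adjusted over the list alone, adjusted p = 0.89 with an estimated correlation). Presynaptic genes rose for 14 of 25 and fell for 1 (15 and 1 adjusted over the list alone), and excitatory neuron genes rose for 10 of 15 and fell for 2 (11 and 2 adjusted over the list alone; adjusted p = 0.72 with an estimated correlation for each). Hippocampus and cortex genes rose for 13 of 15 and fell for 1 (13 and 1 adjusted over the list alone, adjusted p = 0.64 with an estimated correlation). Myelin genes fell for 8 of 16 (9 adjusted over the list alone, adjusted p = 0.98 with an estimated correlation), against 0 of 16 with ShK-223 alone (camera adjusted p = 0.516) and 11 of 16 with PAP-1 alone. The myelin (adjusted p = 0.16) and cytokine (0.0818) calls ended without Control 2 and PAP-1 1, and held in 7 and 6 of 9 fits without 1 library. Beside these groups, the cerebellar index was 0.199 or below in all 6 inhibitor libraries and 0.858 or more in PBS. Kcna3 was at 2.56 CPM in Control 2, against 3.24 and 3.70 CPM in Control 1 and 3. With the batch as a term 3659 genes passed (median 0.63 against 0.70). With the cerebellar index 0 passed at a median of 0.11, where Trem2, P2ry12 and the homeostatic, plaque-associated, complement and ribosomal lists turned to lower values and the cerebellum list to higher ones. With the index the cholesterol (camera adjusted p = 0.158), antigen-presentation (0.670) and cytokine (0.487) calls ended. Within batches C and CH 99.97% and 99.99% of the called genes, which these libraries helped to select, kept their direction.

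Across the 15061 genes, which are not independent replicates, the ShK-223 and PAP-1 changes against PBS correlated with Pearson r = 0.91 and Spearman rho = 0.92. Unchanged groups simulated against shared PBS libraries gave r = 0.51. The covariance was 0.913 against a simulated 0.0699. Higher genes shared by both numbered 2430 of 2835 and 3182, where independent lists would share 599. Lower genes numbered 2579 of 3061 and 3407, where they would share 692. In the simulations a mean of 0 genes was called in both. The 3 PBS libraries are too few to divide between the comparisons, and part of the excess may come from the shared controls. The simulation held no tissue difference between libraries, while all 3 PBS libraries had a cerebellar index of 0.858 or more. The overlap therefore does not part a shared response to the blockers from cerebellar transcript in PBS.

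PBS was compared with Control, and 756 genes passed, 62 higher and 694 lower in PBS (8.20% higher). Without Control 2, 6721 passed with 51.7% higher, and DESeq2 called 2951 with 30.1% higher. Some genes of cortical neurons were lower in PBS. Ntsr1, a neurotensin receptor of deep-layer cortical neurons, was at 0.915 ± 0.451 CPM in PBS and 9.92 ± 0.716 CPM in Control (-3.41, SE 0.33, adjusted p = 0.0104), and Neurod6 (-1.73, SE 0.35) and Thy1 (-1.28, SE 0.31, adjusted p = 0.0466) were also lower. The excitatory neuron list fell for 4 of 15 (10 lower and 1 higher adjusted over the list alone, adjusted p = 0.79 with an estimated correlation). Synaptic members were lower too: 4 of 25 presynaptic and 4 of 26 postsynaptic genes fell (10 and 9 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation for each), with Syn1 at -0.86 (SE 0.18) and Grin2b at -2.19 (SE 0.44).

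Complement genes C1ra (-2.41, SE 0.43) and C1s1 (-1.84, SE 0.41) fell, 2 of 19 of their list (14 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation). Cholesterol synthesis fell for 3 of 22 (13 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), with Fdft1 at -1.11 (SE 0.27). The striatum list fell for 1 of 15 (11 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), the gene Meis2 (-1.86, SE 0.47). The hippocampus and cortex list fell for 2 of 15 (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.79 with an estimated correlation), and the lysosome list for 1 of 29 (11 lower and 2 higher adjusted over the list alone, adjusted p = 0.83 with an estimated correlation). The ribosomal list (median -0.40) and the plaque-associated list (median -1.06) were called lower with 0 of 41 and 0 of 30 genes passing, 0 adjusted over the list alone and an adjusted p = 0.83 with an estimated correlation for each. No homeostatic microglia gene passed over all genes, and 17 of 19 were lower adjusted over the list alone (median -1.36, adjusted p = 0.83 with an estimated correlation), among them P2ry12 (-1.34, SE 0.40). Trem2 (-1.68, SE 0.62, adjusted p = 0.0982), Cst7 (-1.97, SE 0.73), Kcna3 (-0.38, SE 0.22) and App (-0.23, SE 0.09) did not pass. Beside all these groups, the cerebellar index was 0.0543, 0.812 and 0.0525 in Control 1, 2 and 3, and the cerebellum list was the 1 list called higher (0 of 16 genes passing, adjusted p = 0.83 with an estimated correlation), with Calb1 at 1.17 (SE 0.51).

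The other leading genes were lower for Ntn5 (-4.50, SE 0.57), Glp2r (-3.99, SE 0.78), Rxfp1 (-3.52, SE 0.60), Cntnap3 (-3.48, SE 0.72), Ano2 (-3.43, SE 0.82), Wnt2 (-3.41, SE 0.70) and Krt80 (-3.33, SE 0.69). They were higher for Strc (1.72, SE 0.37), Kcnk12 (1.55, SE 0.38), Eva1c (1.47, SE 0.35), Pthlh (1.19, SE 0.26), Spsb3 (0.99, SE 0.25), Hebp2 (0.96, SE 0.24), Xkr6 (0.93, SE 0.22) and Mroh2a (0.92, SE 0.22). The count fell to 0 without Control 1, Control 3 or PBS 3, to 1 without PBS 2, to 0 with the 2 groups alone, to 2 with the batch term (median of the called genes 1.11 against 1.21) and to 0 with the cerebellar index (median 0.40). With the index the plaque-associated (adjusted p = 0.00426), ribosomal (0.000795), striatum (0.0307), homeostatic (0.0561), complement (0.527) and lysosome (0.053) lists turned to higher values in PBS, and the cerebellum list to lower ones (0.00231). The cholesterol (camera adjusted p = 0.463), presynaptic (0.0530) and postsynaptic (0.101) calls ended with the index. The postsynaptic call also ended without Control 2 and PAP-1 1 (0.0554). It held in 4 of 6 fits without 1 library, the presynaptic call in 5 and the lysosome call in 3. Within batches C and CH all 756 called genes, which these libraries helped to select, kept their direction, with medians of 0.47 and 1.59 (log2) against 1.21 over all libraries.

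ShK-223 and PAP-1 were compared with each other, and 0 genes passed in edgeR, with 684 at an unadjusted p under 0.05 and 5 called by DESeq2. Myelin genes had a median difference of 0.89, higher with ShK-223, for example Myrf (1.09, SE 0.33) and Mbp (0.91, SE 0.33). Of these, 10 of 16 passed adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). Immediate early genes had a median of -0.86, for example Fosb (-2.31, SE 0.68), with 0 of 25 adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). Striatal genes had a median of 1.69, for example Drd2 (3.09, SE 1.06), with 0 of 15 adjusted over the list alone (adjusted p = 0.89 with an estimated correlation). The smallest p-values belonged to Bex1 (-0.57, SE 0.11), Stac2 (0.63, SE 0.13), Lypd1 (-1.54, SE 0.32), Plekhh2 (0.48, SE 0.10), Eml1 (0.33, SE 0.07), Prxl2b (-0.50, SE 0.11), Pml (0.58, SE 0.13) and the haemoglobin gene Hbb-bs (1.98, SE 0.47), each with an edgeR adjusted p = 0.984. The other called lists had no gene past the test. Plaque-associated microglia (median 0.20), interferon response (0.67), complement and Fc receptors (0.23), choroid plexus (1.32) and thalamus (0.60) were higher with ShK-223. Ribosomal proteins (-0.09), cholesterol synthesis (-0.14) and cerebellum (-1.79) were lower. Each of these had adjusted p = 0.89 with an estimated correlation and 0 genes adjusted over the list alone, or 1 for thalamus. The interferon list had a centred mean of 1.86, -0.30 and -0.64 in the ShK-223 libraries and 0.92, -0.47 and -0.73 in PAP-1, and turned lower, without passing, when ShK-223 1 was left out. The choroid plexus list had -1.44, 2.08 and 0.61 against 1.09, -1.90 and -1.29. The cerebellum list was at 1.36 in PAP-1 1, at -2.23 and -2.11 in PAP-1 2 and 3 and at -2.23, -2.64 and -2.19 in ShK-223. Without Control 2 and PAP-1 1 the cerebellum (adjusted p = 0.177), cholesterol (0.361), ribosomal (0.599) and thalamus (0.279) calls ended. The interferon, choroid plexus, complement, cholesterol, thalamus, amyloid processing and red blood cell calls held in 3 of 6 fits without 1 library, the cerebellum call in 4 and the plaque-associated and ribosomal calls in 2. Amyloid processing (0.09) and red blood cell genes (0.28, 3 of 7 adjusted over the list alone) had an adjusted p = 0.55 with an estimated correlation, and nuclear oxidative phosphorylation (-0.09) an adjusted p = 0.85 with an estimated correlation. Beside these, the striatal index was 0.160, 0.698 and 0.414 in ShK-223 and 0.149, 0.168 and 0.210 in PAP-1.

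ShK-223 was compared with Control, and 0 genes passed in edgeR, with 1027 at an unadjusted p under 0.05 and 9 called by DESeq2. Fibcd1, a gene of hippocampal neurons, was at 24.1 ± 5.87 CPM with ShK-223 and 5.85 ± 1.53 CPM in Control (2.04, SE 0.34, adjusted p = 0.722). The hippocampus and cortex list had a median of 0.40 with 3 of 15 higher adjusted over the list alone (adjusted p = 0.20 with an estimated correlation), including C1ql2 (3.14, SE 0.68) and Neurod6 (1.08, SE 0.33). Immediate early genes had a median of 0.57, for example Egr1 (1.04, SE 0.38), with 0 of 25 adjusted over the list alone (adjusted p = 0.79 with an estimated correlation). Antigen presentation had a median of 0.43, for example H2-Aa (1.98, SE 0.57), with 0 of 21 adjusted over the list alone (adjusted p = 0.79 with an estimated correlation). Its centred mean was 1.14 in ShK-223 1 and 0.13 and 0.04 in ShK-223 2 and 3. Other genes with the smallest p-values were Nt5dc3 (0.56, SE 0.10), Mctp1 (-0.65, SE 0.13), Nrn1 (0.78, SE 0.16), Pbx3 (-0.90, SE 0.18), P2ry1 (-1.60, SE 0.34), Pde1c (-1.91, SE 0.40) and Golga7b (0.34, SE 0.07), none of which passed. Mbp differed by -0.12 (SE 0.33). Presynaptic (median 0.16) and excitatory neuron genes (0.49) were called higher as lists, with 0 and 1 adjusted over the list alone (adjusted p = 0.49 with an estimated correlation for each). Postsynaptic (0.17) and thalamus genes (0.48) were called higher and cell cycle genes (-0.66) lower, with 1, 0 and 0 adjusted over the list alone (adjusted p = 0.79 with an estimated correlation for each). The cell cycle list was at 1.31 in Control 1, at -0.24 and 0.13 in Control 2 and 3 and at 0.07, -0.05 and -0.27 in ShK-223, and its call ended without Control 1. Cytokine (0.39) and cholesterol synthesis genes (0.16) were called higher with 0 adjusted over the list alone (adjusted p = 0.99 with an estimated correlation for each). Without Control 2 and PAP-1 1 the antigen-presentation (adjusted p = 0.0574), cytokine (0.449), cerebellum (0.348) and cholesterol (0.734, turned lower) calls ended. In that fit camera at the preset correlation called the homeostatic (0.000406) and plaque-associated (0.00162) microglia lists lower with ShK-223. An estimated correlation was not run there. The homeostatic centred mean was 1.00 and 0.55 in Control 1 and 3 and 0.28, 0.40 and 0.52 in ShK-223. The plaque-associated mean was 0.77 and 0.57 against 0.47, 0.22 and 0.52. The cytokine and thalamus calls held in 3 of 6 fits without 1 library, the antigen-presentation and cholesterol calls in 4 and the cerebellum and cell cycle calls in 5. Beside these, the cerebellum list had a median of -3.87, with 15 of 16 lower adjusted over the list alone (adjusted p = 0.87 with an estimated correlation).

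PAP-1 was compared with Control, and 0 genes passed in edgeR, with 2290 at an unadjusted p under 0.05 and 378 called by DESeq2. Fibcd1 had the smallest p, at 47.5 ± 19.4 CPM with PAP-1 and 5.85 ± 1.53 CPM in Control (3.02, SE 0.35, adjusted p = 0.0688). Immediate early genes had a median of 1.48, for example Egr2 (3.45, SE 0.83) and Fosl2 (1.69, SE 0.27). Of these, 22 of 25 were higher adjusted over the list alone (adjusted p = 0.49 with an estimated correlation). The centred mean was 1.77, 1.11 and 0.28 in PAP-1 and -0.99, -0.28 and 0.09 in Control. Myelin genes had a median of -1.05, for example Trf (-1.24, SE 0.26), Ugt8a (-1.47, SE 0.37) and Mbp (-1.03, SE 0.33). Of these, 14 of 16 were lower adjusted over the list alone (adjusted p = 0.61 with an estimated correlation). The hippocampus and cortex list had a median of 0.80 with 5 of 15 higher adjusted over the list alone (adjusted p = 0.49 with an estimated correlation), C1ql2 at 3.74 (SE 0.69). Striatal genes had a median of -2.14, for example Drd2 (-3.88, SE 1.08) and Pde10a (-2.29, SE 0.62), with 4 of 15 lower adjusted over the list alone (adjusted p = 0.98 with an estimated correlation). Cholesterol synthesis (median 0.28) and postsynaptic genes (0.14) were called higher and cell cycle genes (-0.51) lower as lists, with 0 adjusted over the list alone (adjusted p = 0.98 with an estimated correlation for each). The cell cycle list was at 1.31 in Control 1, at -0.24 and 0.13 in Control 2 and 3 and at 0.09, -0.33 and -0.12 in PAP-1, and its call ended without Control 1. Presynaptic genes (0.21, 2 of 25 adjusted over the list alone, adjusted p = 0.59 with an estimated correlation) were called higher and amyloid processing genes (-0.13, 4 of 24 adjusted over the list alone, adjusted p = 0.55 with an estimated correlation) lower. Nt5dc3 (0.73, SE 0.10), Zfp697 (0.90, SE 0.13), Pbx3 (-1.19, SE 0.19), Lrrc1 (-1.15, SE 0.19), Adamts4 (-1.38, SE 0.23) and Eml1 (-0.40, SE 0.07) did not pass. Beside these, the striatal index was 0.997 and 0.828 in Control 1 and 3 and 0.119 in Control 2. With the cerebellar index as a term 7 genes passed. Without Control 2 and PAP-1 1 5 passed, and the cholesterol list was no longer called (adjusted p = 0.669). In that fit camera at the preset correlation called the homeostatic (2.0e-05) and plaque-associated (9.8e-08) microglia lists lower with PAP-1. An estimated correlation was not run there. The homeostatic centred mean was 1.00 and 0.55 in Control 1 and 3 and 0.14 and 0.19 in PAP-1 2 and 3. The plaque-associated mean was 0.77 and 0.57 against 0.11 and -0.21. The postsynaptic call held in 3 of 6 fits without 1 library, the striatum and amyloid processing calls in 4 and the cholesterol and cell cycle calls in 5.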

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

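With the cerebellar index as a term, chosen after the data were seen, no gene was called in any comparison with PBS, and the sign of the log2 fold change turned for many named genes. For ShK-223 against PBS the values became Gabra6 0.99, Cbln3 0.60, Lbx1 4.34, Nrk 0.0255, Fat2 0.46, Skor2 1.23, Ppp1r17 1.10, Cst7 -1.27, Trem2 -0.67, Apoe -0.49, Itgax -1.39, P2ry12 -0.32, Gfap -0.65, Snap25 -0.0314, Calb1 0.0695, Itpr1 0.19, Lpl -0.61, Cd68 -0.38, Slc1a3 0.0545, Rpl10 -0.20 and Foxp1 -0.31. For PAP-1 against PBS the values became Skor2 4.27, Il22b 2.39, Uncx 2.32, Zfp385c 2.00, Hes3 2.54, Car8 1.76, Bcl2l15 1.52, Lhx5 2.44, Cst7 -1.38, Trem2 -0.55, Apoe -0.39, Itgax -1.42, P2ry12 -0.47, Gfap -0.68, Lpl -0.67, Cd68 -0.52 and Fcgr3 -0.37. For both inhibitors against PBS the values became Cst7 -1.33, Trem2 -0.61, P2ry12 -0.39 and Sycp1 1.39. For PBS against Control the values became Trem2 0.38, Cst7 0.77, Calb1 -0.25 and Meis2 0.11. The median log2 change of the called genes shrank from 0.794 to 0.0962 for ShK-223, 0.758 to 0.186 for PAP-1, 0.698 to 0.106 for both and 1.21 to 0.396 for PBS against Control. The index nearly marks out PBS, so this term also takes away power. For ShK-223 against PBS it made the SE larger by a median factor of 1.75. In simulation it left 47.0% of 4-fold changes recovered, but those data held no tissue difference, so this share may not hold here. The turned signs are uncertain. Called lists turned as well, those of homeostatic and plaque-associated microglia, complement and Fc receptors, ribosomal proteins and cerebellum for both inhibitors and for each alone. Other calls ended without turning. These were antigen presentation for both and for each alone, cytokine and cholesterol genes for ShK-223 and for both, and amyloid processing for PAP-1. The immediate early, synaptic, excitatory neuron and hippocampus and cortex calls of the blockers against PBS held, as did cholesterol for PAP-1 (camera adjusted p = 0.0276). The term called 7 genes for PAP-1 against Control.

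The batch term left 4, 2752 and 3659 called genes for ShK-223, PAP-1 and both against PBS, 2 for PBS against Control (median log2 change 0.693, 0.724, 0.634 and 1.11) and 7 lists for ShK-223 against PAP-1. Leaving out 1 library gave 3156 to 4854 for ShK-223 (3752 without PBS 3, 3744 without ShK-223 3), 3934 to 5733 for PAP-1, 5068 to 7433 for both, 0 to 6721 for PBS against Control (1 without PBS 2), 0 to 1 for ShK-223 against PAP-1 and against Control and 0 to 2 for PAP-1 against Control. PBS against Control gave 2951 with DESeq2, 3 with limma-voom, 137 with RNA integrity, 0 with its groups alone, 3271 at a threshold of 0.1 and 7278 without Control 2 and PAP-1 1, of which 51.5% were higher. The comparisons without PBS gave 5, 9 and 378 with DESeq2, and PAP-1 against Control gave 1 without a filter, 1 at a threshold of 0.1 and 5 without the same libraries.

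Every list call was lost (0 lists) with an estimated correlation. Fry called 9, 11, 11 and 3 lists in the comparisons with PBS and 0 in the others. Leaving out 1 library gave 14 to 16, 11 to 16, 13 to 15, 12 to 15, 7 to 18, 10 to 17 and 7 to 15 lists in the order of the report, with 9 for ShK-223 against PAP-1 without ShK-223 1. Against Control, the index term gave 18 lists for ShK-223 and 17 for PAP-1, and removal of Control 2 and PAP-1 1 gave 17 and 19. The correlation between the inhibitor changes was 0.887 with the batch term, 0.874 with the index, 0.940 at a mean log2 CPM of at least 5 and 0.899 to 0.926 without 1 PBS library. Of 3051 alternative values for 178 gene results, 2397 stayed alike, 543 were weaker, 64 stronger and 47 turned sign, among them Mbp for ShK-223 against Control, which ran from -0.29 to 0.12 when 1 library was left out, the latter without ShK-223 1. The cause was not tested for these. Sex as a term was not run.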

Other observations

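Markers of small brain structures varied between single mice of the same group. Ttr, the transthyretin made by choroid plexus, ran from 3.93 CPM in ShK-223 1 to 1217 CPM in ShK-223 2. The pituitary hormones Gh and Prl were at 24.4 and 44.8 CPM in PBS 3 and at 13.8 and 21.4 CPM in PAP-1 2, against 1.44 and 3.40 CPM or less elsewhere. Hoxb5, a gene of the hindbrain and spinal cord, was at 7.93 CPM in PBS 3 and at 0.207 CPM or less in all others. Slc6a5, the glycine transporter of hindbrain neurons, was at 112 CPM in PAP-1 1 and 111 CPM in PBS 3, and at 0.0536 CPM in ShK-223 3.

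Activity and immune genes also stood apart in single mice. Fos and Npas4, induced by neuronal firing, were at 297 and 306 CPM in PAP-1 1, against 28.8 and 24.2 CPM in PAP-1 3. The interferon-response list had a centred mean of 1.86 in ShK-223 1, and -0.30 and -0.64 in ShK-223 2 and 3. Its antigen-presentation mean was 1.14, against 0.13 and 0.04.

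The blocker groups differed from PBS in 7548 called genes, and the tests of cerebellar tissue, blockade, depth and batch were chosen only after the result was seen. Cerebellar tissue in PBS could make most of the difference. Across genes, Control 1 and 3 minus Control 2 followed ShK-223 minus PBS with r = 0.834, and shares no library with it. The r was 0.654 among the 12213 genes under 2-fold between ShK-223 and PBS. It was 0.761 for PAP-1 2 and 3 minus PBS over all tested genes. If Control 2 were a mislabelled PBS library, these values would not part tissue from treatment. Called genes were also oriented by their direction against PBS. Their median difference between 5 blocker libraries (without PAP-1 1) and Control 1 and 3 was 0.0438 (log2). Against PBS it was 0.691, so the share was 0.0634. Differences in opposite directions cancel in this median, so single genes may differ more from Control. If Control and PBS mice were otherwise alike, the low share would argue against Kv1.3 blockade as the source of most of the difference from PBS. What sets Control apart from PBS is not given, and a smaller effect of blockade stays open. These libraries were picked by their low cerebellar transcript, which many called genes follow, and are not study groups. Library depth is an unlikely source of most of the difference from PBS, as 0.963 of the calls stayed at equal totals. The labelled batch is an unlikely source of most of it too: over all tested genes ShK-223 1 and 3 minus PBS 2 within CH followed PAP-1 2 minus PBS 1 and 3 within C with r = 0.871, and 4861 genes called without the CH libraries had a median log2 change of 0.910 within CH and 0.835 outside it, while the batch term kept 0.482 of the calls at a median of 0.634 against 0.698 with SE 1.23 times as large.

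Plaque-associated and homeostatic microglia genes were higher with the blockers than with PBS, and both tests here were chosen only after the result was seen. Cerebellar tissue in PBS may account for it, since the median over both lists was 1.65 (log2) higher in Control 1 and 3 than in Control 2, against 1.26 for both inhibitors minus PBS, with the same limit on the label of Control 2. If Control and PBS mice were otherwise alike, Kv1.3 blockade as the source would raise these genes above Control 1 and 3 as well. What sets Control apart from PBS is not given, so the outcome cannot decide on its own. In 5 blocker libraries (without PAP-1 1) the median against Control 1 and 3 was -0.46, with 2 of 48 genes higher. These libraries were picked by their transcripts and are not study groups, so an effect of blockade within a matched region stays untested.

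On average PAP-1 libraries held less myelin and striatal and more immediate early transcript than Control libraries, though no gene passed in edgeR. Control 2, with a striatal index of 0.119, lay below the PAP-1 libraries at 0.149 to 0.210. All tests here were chosen only after the result was seen. PAP-1 was not needed for low striatal transcript: the median of the striatum list was -2.05 (log2) in ShK-223 1 relative to ShK-223 2 and 3, and -3.88 in Control 2 relative to Control 1 and 3. ShK-223 1 was picked after its transcripts were seen. Control 2 is not a like case, with a cerebellar index of 0.812 against 0.0523 and 0.0511 in PAP-1 2 and 3. Regional make-up may be a source of the lower myelin and higher immediate early transcript. PAP-1 2 and 3 minus Control 1 and 3 followed ShK-223 1 minus ShK-223 2 and 3 with r = 0.218, while the myelin median was -0.96 in the latter and -1.06 in the former, and the immediate early median 0.49 and 1.02. This is 1 library without PAP-1, and myelin in Control 2 was at -0.45, so regional make-up and an effect of PAP-1 cannot be told apart.

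The splits were planned before the results were seen. The 10 splits of 2 groups of 3 are too few to judge by. The real value was 5896 for ShK-223 against PBS, 6589 for PAP-1 against PBS and 756 for PBS against Control, each reached by 1 split, with a highest other of 0, 0 and 1, and 0 in the other comparisons, reached by all 10. For both inhibitors against PBS, 1 of 84 splits had as many called genes as the real 7548, and the highest other had 2295. In each split the libraries left over were divided in order into 2 groups of 3. Only the real split sets the 3 PBS libraries, all high in cerebellar transcript, apart, so the count does not part treatment from tissue.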
